A study of Homo sapiens with 4 samples.

How the data were processed

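Poly(A)+ RNA of LX-2 cells, an established line of human hepatic stellate cells, was treated with bisulfite and sequenced in 4 libraries. Bisulfite turns unmodified cytosine into uracil, which is read as thymine, while 5-methylcytosine (m5C) stays cytosine, so a cytosine in a read is an unconverted base. Per the labels, 2 libraries came from untreated cells and 2 from cells given TGF-β1 at 5 ng/ml for 24 h, labelled as biological replicates 1 and 2 of each group. RNA conversion used the EZ RNA Methylation kit and libraries were made with the KC UMI RNA Library kit, per the labels' protocols. Fastp 0.23.0, Bismark 0.22.3 and the build hg38 are named in the submitters' processing notes with no role or order. Alignment settings, the use of the molecular identifiers, the annotation release and the read length are not given in the sources used here. Without that, reads cannot be taken as independent molecules, so every binomial interval covers counting error only. Incomplete conversion, folded RNA that resists it and misaligned reads leave unconverted bases as m5C does, and the values cannot separate these.

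Each deposited file lists cytosines by position, strand, annotated gene and element, with the count of unconverted and the count of converted reads, per the file headers. The deposited methylation level is a fraction, equal to the unconverted count over the coverage within 0.0005, and levels are given as percentages here. The deposited p-value of each site equals the upper binomial tail of the unconverted count at 1 error rate per library, 1.57% and 1.49% in the untreated and 1.73% and 1.61% in the TGF-β1 libraries; how the authors set that rate is not given in the sources used here. Those p-values were not used further. In every file the lowest unconverted count was 1 and the lowest coverage 5, so cytosines without an unconverted read are not listed, and a listed level at low coverage lies above the true mean of such sites. Replicates were deposited separately. Replicate libraries had equal coverage at 2.04% (untreated) and 1.70% (TGF-β1) of tested sites, and the chi-square of their counts per site was 0.967 for the untreated and 1.04 for the TGF-β1 pair, against 1.00 to 1.10 for pairs across groups. They were treated as separate libraries.

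A candidate m5C site had coverage of at least 20, at least 3 unconverted reads and a level of at least 10%. Counts of candidates were made over the cytosines with coverage of at least 20 in all 4 libraries, so that the same cytosines were counted in each library; depth above that minimum still enters, and thinning to 20 reads lowered the ratio of group means from 1.09 to 1.05. A candidate in all 4 libraries was called lone when no other such candidate lay within 25 bases on its strand, and clustered with 2 or more; the window was fixed in advance and the class of lone sites was added after the data were seen. Library values were compared with a two-sided exact permutation test, which for 2 against 2 libraries has 6 arrangements and cannot give p below 0.33. Sites with coverage of at least 20 in all 4 libraries and a pooled level from 5% to 95% were tested on their counts. The test was that of edgeR 4.0.16 (quasi-likelihood test, methylation design) in R 4.3.3, adjusted by Benjamini-Hochberg with a threshold of 0.05. Since only cytosines with an unconverted read are listed, every such cytosine had at least 1 unconverted read in each library. Sites fully converted in 1 or more libraries were therefore left out of the candidate counts on shared cytosines, the overlaps and the site test. Set against its own simulation with 200 changed sites among 92558, the edgeR test made 0 false calls. It recovered 0% of rises of 10 points and 42% of rises of 30 points. Of falls set at 20 and 40 points it recovered 32% and 58%. Falls stopped at a floor, so at sites of low level they were smaller than set. Size and direction therefore cannot be told apart in these shares. At sites with coverage of at least 100, the shares for 10, 20, 30 and 40 points were 0%, 70%, 100% and 100%. The simulation drew sites independently with the same spread for all. Its false calls therefore say nothing about runs of neighbouring sites that share reads, or about sites where a single library deviates. Levels of preset gene lists were set against 10000 random sets of tested sites matched on level and coverage. Fisher's exact test compared sequence contexts over sites, which are not independent replicates. The sequence of hg38 was not used here: the guanine-rich context of NSUN2 was read only as a G at the second base after the cytosine, from the listed trinucleotide, and TCCA from the trinucleotides of neighbouring listed positions.

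Coverage of a gene's cytosines served as a stand-in for RNA abundance. This was planned only for files that list every covered cytosine, a condition that was not met. It was run instead on exonic cytosines listed in all 4 libraries, at least 10 per gene, a choice made after the data were seen. Genes switched on or off strongly have no such cytosines and are left out, and folds may be understated. Each read counts at several cytosines. Coverage was summed per gene, scaled to counts per 1e6 of shared coverage (CPM) and tested as log2(CPM + 1) with limma 3.58.1 (trend), for genes with at least 1 CPM in at least 2 libraries. Folds on this scale understate changes of low genes. In its simulation of 200 changed genes among 7095, 157 genes were called, 6 of them falsely, and 31.8%, 94.0% and 100% of changes of 1.5, 2 and 4 fold were recovered. That simulation gave every gene the same median spread, independent between genes and without trends along gene properties. Its shares therefore do not hold for genes of wider spread, some of which changed more than 4 fold here without being called. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one. DESeq2 1.42.0 and edgeR on rounded mean coverage per shared cytosine were alternatives. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.

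The groups, tests, gene lists, alternatives and the rule for named items were fixed before the data were examined, and alternatives added later are named as such in the closing section. The rule named, in each direction, the 10 called sites with the largest difference of group means among those where both treated libraries lay on the same side of both untreated ones, called sites in a preset list (the mitochondrial ones are given together), and the 10 sites with the highest mean level, at most 1 per gene. For gene coverage it named the 10 called genes of largest fold in each direction, up to 4 called members per list, and ACTA2, COL1A1, CCN2, NSUN2, NSUN6, ALYREF and YBX1 in any case; some genes that the rule named are not reported here. Alternatives covered coverage minimums of 10 and 50, level minimums, thinning to 20 reads, clustered sites left out, other tests and scalings, a replicate block and leaving out each library. Each library left out in turn leaves a group with 1 library, which is then assumed to vary like the other group. Mitochondrial positions carry only upstream or downstream annotations in the files. Processed pseudogenes can share reads with their parent genes, so their values are uncertain. The labels name no batch, so group and library handling cannot be told apart. At most, p-values of the library, site and gene tests measure the spread between these cultures. In the site test that spread was shared over all tested sites (edgeR prior degrees of freedom 215). A site's p therefore rests mostly on the shared value and little on its own libraries. P-values of Fisher's test, of the random sets and of camera at the preset correlation are taken over sites, reads or genes. They do not measure the spread between cultures, and neighbouring sites share reads. Lists of hepatocyte, endothelial and macrophage markers, fixed to detect other liver cells, had 0 measured members in gene coverage and were not tested, nor was the mitochondrial list there.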

Results

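The data describe cytosine conversion in RNA of LX-2 hepatic stellate cells, the liver cells that become matrix-producing myofibroblasts when activated, without treatment and after TGF-β1, a cytokine that drives this activation. The stated question was how m5C changes after the stimulus. Each group held 2 libraries. The untreated libraries listed 2794033 and 3197805 cytosines with a summed coverage of 357527043 and 373236982, and the TGF-β1 libraries listed 1926668 and 1986982 with 220303409 and 270054533. Median coverage per listed cytosine was 59 and 54 in untreated and 52 and 59 in TGF-β1 libraries. Of 4858381 positions listed anywhere, 17.2% were listed in all 4 libraries, and 766690 had coverage of at least 20 in each.

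The share of unconverted reads over listed cytosines differed little between the groups. It was 2.62% ± 0.0505 (SD, n = 2) in untreated and 2.73% ± 0.0834 (SD, n = 2) in TGF-β1 libraries, a difference of 0.114 points (exact permutation test, two-sided p = 0.33, the smallest that 2 against 2 libraries allow). Only cytosines with an unconverted read enter this share, candidate sites included, so it lies above the background under a site level. At cytosines with coverage of at least 500 in the library, the share was 1.94% and 1.97% in untreated and 2.06% and 2.06% in TGF-β1 libraries. Candidate m5C sites numbered 37291 and 39490 in the untreated and 43373 and 40285 in the TGF-β1 libraries, a ratio of group means of 1.09 (exact permutation p = 0.33). That permutation test cannot pass a threshold of 0.05 with these libraries. Over each library's own listed cytosines the direction was opposite, with 76141 and 86209 candidate sites in untreated and 57396 and 60549 in TGF-β1 libraries. The number of cytosines listed per library enters those counts.

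**Figure D1:**
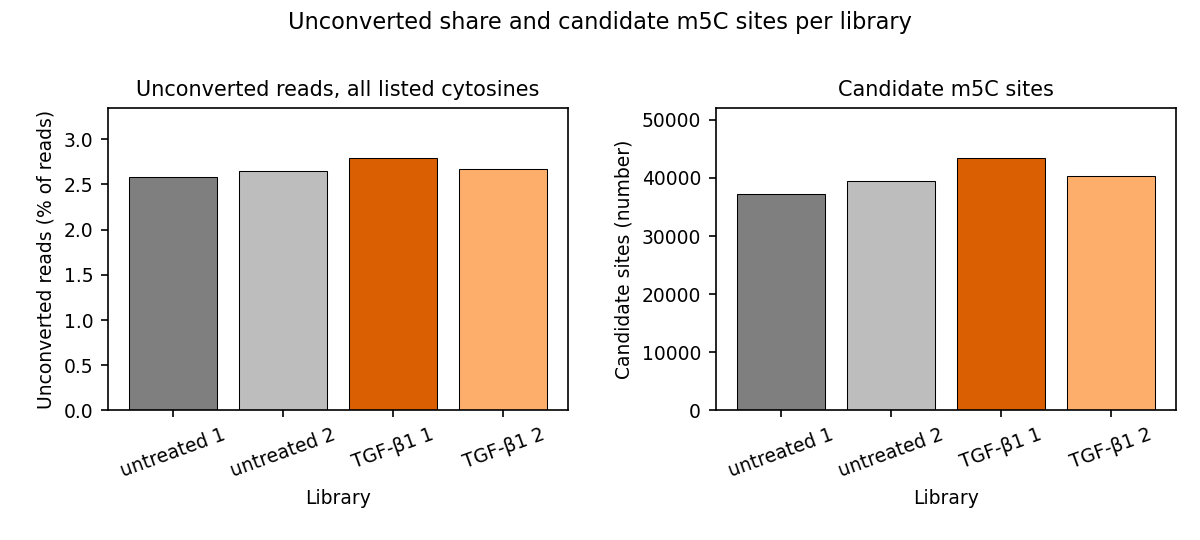
Bars give, for each of the 4 libraries, the unconverted share of reads over all listed cytosines (left, percent) and the number of candidate m5C sites among the 766690 cytosines covered in all libraries (right). Candidate numbers run from 37291 in an untreated library to 43373 in a TGF-β1 library.

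Among cytosines with an unconverted read in every library, candidate sites recurred across libraries whatever the treatment. That condition can raise the overlap. Pairs within a group shared a mean Jaccard index of 0.585 and pairs across groups 0.580, and the 6 pairs had an SD of 0.0182, so the groups did not separate. In all, 24089 sites were candidates in every library. Most stood in dense runs: 20420 (84.8%) were clustered in 1899 genes, with a median level of 28.3%, and 2473 (10.3%) were lone in 1917 genes, with a median level of 15.5%. Median levels of clustered sites were 28% in both untreated libraries and 30.6% and 28.2% in the TGF-β1 libraries. Those of lone sites were 15% in both untreated libraries against 16.1% and 15.6%.

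The sites of highest level were unconverted in nearly every read of both groups. The cytosines at chromosome 11 position 119334641 in the 5' UTR of RNF26, chromosome 11 position 76380913 in the 5' UTR of THAP12 and chromosome 16 position 50368797 in the 5' UTR of BRD7 were unconverted in 100% of reads in every library, at coverage from 31 to 179. The coding site of ANKRD33B (chromosome 5, 10564493) averaged 99.7% ± 0.385 and the 3' UTR site of ZMIZ2 (chromosome 7, 44768197) averaged 99.3% ± 0.837 (SD, n = 4). INPPL1, an inositol phosphatase, had 98.9% ± 0.744 in its 3' UTR (chromosome 11, 72238763), MGAT2 98.9% ± 1.32 in its 5' UTR (chromosome 14, 49621124) and SHC1, a signalling adaptor on the list of earlier NSUN2 targets, 98.8% ± 1.40 in an intron (chromosome 1, 154970586). An intron of ENSG00000232555 (chromosome 2, 172165145) had 98.5% ± 1.26 and the coding sequence of UQCRFS1 (chromosome 19, 29213011) 98.3% ± 1.24. All 10 lay in clusters. Positions 839 and 841 of the mitochondrial 12S ribosomal RNA, RNR1 (mitochondrial 1486 and 1488), known for N4-methylcytosine and for m5C respectively, stood at 30.3% ± 1.14 and 50.1% ± 2.44 (SD, n = 4), with coverage from 151 to 315. They lie outside the rule for named sites and were chosen after their values were seen.

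Candidate sites were over-represented in the 5' UTR and in introns. The 5' UTR held 13.3% ± 0.180 of candidates in untreated and 12.9% ± 0.156 in TGF-β1 libraries (SD, n = 2), against 5.09% of the examined cytosines, and introns 14.6% and 14.3% against 10.5%. Coding sequence held 40.0% and 40.5% against 49.9%, and the 3' UTR 15.7% and 15.8% against 14.7%. Exons of noncoding transcripts held 4.41% and 4.66% against 10.0%, upstream regions 5.68% and 5.44% against 4.96%, and downstream regions 6.27% and 6.43% against 4.86%. The shares of the 5' UTR, coding sequence, introns and upstream regions were separated between the groups (exact permutation p = 0.33, its minimum) and those of the other 3 features were not. Of these 4 only introns stayed separated both at a level minimum of 20% and at a coverage minimum of 50. Placement also differed by class among candidates of all 4 libraries. The 5' UTR held 16.0% of clustered and 7.28% of lone sites, and the 3' UTR 13.3% and 22.1%. Introns held 15.2% of clustered and 13.2% of lone sites.

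Lone and clustered sites differed in sequence. A G at the second base after the cytosine, part of the context described for the methyltransferase NSUN2, followed 62.0% of lone sites and 37.1% of cytosines that were candidates in no library (Fisher's exact test over sites, odds ratio 2.77, 95% interval 2.554 to 3.005, p = 2.42e-138). Among clustered sites it followed 41.4% (Fisher's exact test over sites, odds ratio 1.201, p = 1.52e-36). Lone sites were rich in CAG and CGG, and clustered sites in CCC (26.3%) and CCG (16.5%). TCCA, described for the methyltransferase NSUN6, followed 0.357% of all candidates and 0.472% of other cytosines (odds ratio 0.756, 95% interval 0.610 to 0.937, Fisher's exact p = 0.00942), yet among lone sites alone the ratio was turned, 1.64 (19 of 2467 sites, 95% interval 1.04 to 2.58, p = 0.0383). That split by class was added after the data were seen, and among the lone candidates of each library TCCA gave 0.974 and 0.680 in untreated and 0.689 and 0.766 in TGF-β1 libraries. Among candidates of single libraries the G context gave odds ratios of 1.43 and 1.48 in untreated and 1.45 and 1.45 in TGF-β1 libraries, and TCCA 0.787 and 0.718 against 0.701 and 0.686.

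**Figure D2:**
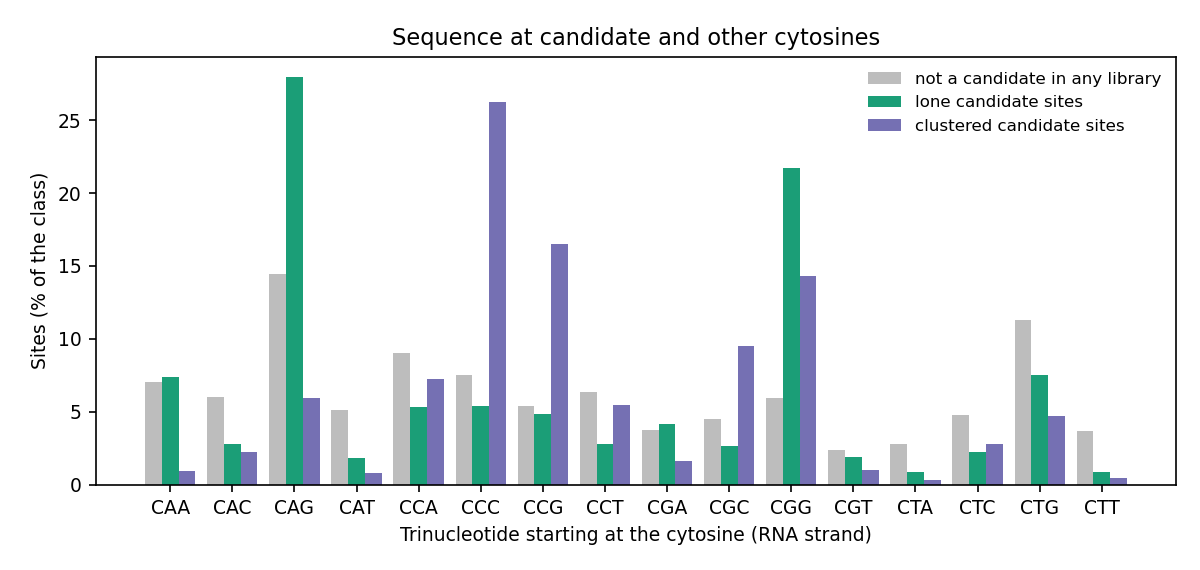
Bars give the share of sites (percent of the class) with each trinucleotide starting at the cytosine, for cytosines that were candidates in no library, lone candidates and clustered candidates of all 4 libraries. Clustered candidates reach 26.3% at CCC and lone candidates stand highest at CAG and CGG.

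Among the tested sites, which had an unconverted read in every library, few positions were called between the groups. They lay mainly in 2 places, the minus strand of the mitochondrial genome and the 5' UTR of CENPB, which encodes a centromere-binding protein. The test recovered 0% of simulated rises of 10 points, so changes of that size can be missed. Of 92558 tested sites, 172 rose and 17 fell (edgeR quasi-likelihood test, adjusted p under 0.05), of which 106 and 12 differed by at least 10 points. Of these, 143 were mitochondrial and 46 nuclear, in 16 genes, 29 of them in CENPB. Both treated libraries lay on the same side of both untreated ones at 137 of the 189, which selection by p favours (chance gives 33.3% for sites not selected). This held at every nuclear call but only at 91 of the 143 mitochondrial ones. Over all tested sites the median difference was 0.43 points (SD over sites 4.16), against -0.585 points between the TGF-β1 libraries themselves.

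In the CENPB 5' UTR neighbouring cytosines moved in opposite directions. The 29 called sites lay on the minus strand of chromosome 20 from 3786476 to 3786561, 26 in the 5' UTR and 3 in coding sequence, with 16 higher and 13 lower. The largest rise was at 3786556, from 5.27% ± 1.498 to 49.1% ± 5.36 (SD, n = 2), and the largest fall at 3786531, from 94.3% ± 0.836 to 45.6% ± 6.65 (SD, n = 2), with edgeR adjusted p of 3.51e-21 and 6.69e-22. Rises of 40.5 to 43.6 points were also named at 3786553, 3786554, 3786557, 3786558, 3786559 and 3786560, and falls at 3786506, 3786520, 3786526, 3786532, 3786533 and 3786534. Averaged over the 9 called cytosines from 3786551 to 3786561 that were under 10% in untreated cells, the level went from 5.25% ± 0.322 to 45.9% ± 4.14 (SD, n = 2), at mean coverages from 96.0 to 337. Over 5 called cytosines from 3786526 to 3786534 it went from 93.1% ± 0.791 to 62.2% ± 4.28. Over 14 cytosines of high level further out, from 3786580 to 3786624, it was 73.3% ± 2.42 and 74.4% ± 3.21, within the spread. These blocks were chosen after their values were seen.

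**Figure D3:**
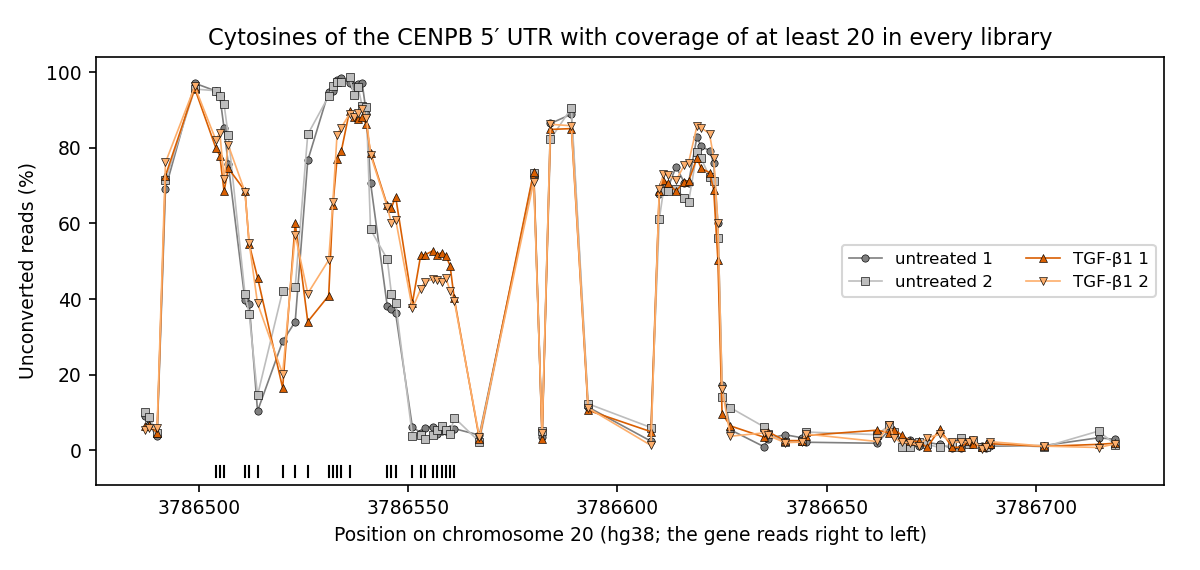
Lines give the unconverted share of reads (percent) at each cytosine of the CENPB 5' UTR covered in all libraries, by position on chromosome 20 (hg38), for each of the 4 libraries; ticks under the lines mark the called sites. From 3786551 to 3786561 the TGF-β1 libraries stand near 45.9% and the untreated ones near 5.25%, while from 3786580 outward the libraries overlap.

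On the mitochondrial genome all 143 called sites were on the minus strand, from 4920 to 15737, and all rose, by a median of 10.9 points (SD over sites 6.46). Among the 839 minus-strand cytosines covered in all libraries, 2.51% and 3.51% of reads were unconverted in untreated and 4.11% and 9.76% in TGF-β1 libraries. Among 1299 plus-strand cytosines the shares were 1.84% and 1.86% against 2.06% and 2.45%. The largest rises were at 6744 and 6745, annotated downstream of MT-TS1, where the level at 6744 was 2.44% and 15% in untreated and 17.2% and 71.4% in TGF-β1 libraries, at coverage from 28 to 41. The group means at 6745 were 8.97% ± 9.07 and 43.1% ± 31.7 (SD, n = 2). These calls needed both untreated libraries and TGF-β1 replicate 2: without any 1 of these 3, 0 mitochondrial sites were called by edgeR (4386 of all tested sites had an unadjusted p under 0.05 without TGF-β1 replicate 2), and without TGF-β1 replicate 1 164 were. The median difference of the mitochondrial list stayed at 4.76 and 6.76 points without an untreated library, against 5.57 with all, but went to 1.23 without TGF-β1 replicate 2.

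**Figure D4:**
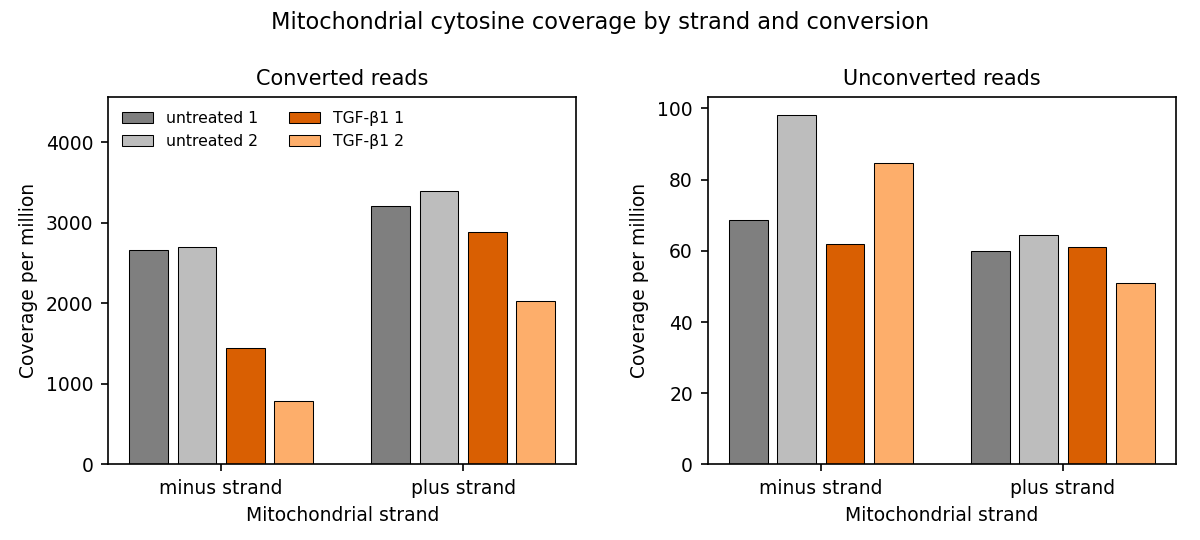
Bars give mitochondrial coverage in CPM (counts per 1e6 of shared coverage), split into converted reads (left) and unconverted reads (right), for the minus and plus strands in each of the 4 libraries. Converted minus-strand coverage is 2664 and 2704 in untreated and 1444 and 784 in TGF-β1 libraries, while unconverted coverage is 68.6 and 98.2 against 61.9 and 84.7.

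Outside these places the largest change was in an intron of TPM1, a tropomyosin gene of the contractile apparatus and the matrix list (chromosome 15, 63044023), which rose from 39.1% ± 7.17 to 74.2% ± 3.16 (SD, n = 2; edgeR adjusted p = 0.00912) at coverage from 25 to 47. A site in the 3' UTR of JPH2 (chromosome 20, 44112533) fell from 16.6% ± 1.60 to 2.27% ± 0.564 (adjusted p = 0.0125), and 2 sites upstream of the microRNA gene MIR6753 (chromosome 11, 68042998 and 68043000) fell from 30.1% ± 11.5 to 5.56% ± 3.45 and from 25.1% ± 4.95 to 3.78% ± 2.51. Single sites were called in RTEL1, SF1, MYBL2, AMIGO2, BTBD2, SPG21, FOXD1, RELL2 and 3 processed pseudogenes, and 2 in the 3' UTR of APOL1, where the level at 36266841 of chromosome 22 was 39.9% and 36.0% in untreated and 58.5% and 59.0% in TGF-β1 libraries. These lie outside the rule for named sites. The number of calls rested on single libraries: without an untreated library it was 10 or 13, without TGF-β1 replicate 1 193, and without TGF-β1 replicate 2 21. A quasi-binomial logistic model fitted to each site alone called 0 sites, with 4862 at an unadjusted p under 0.05.

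Among the preset gene lists, only the mitochondrial genome stood apart in level. Its 474 tested sites had a median difference of 5.57 points, against 0.318 points in matched random sets (permutation test over sites, not libraries, adjusted p = 0.0011, the smallest that the random sets can give over 11 lists). Its median was 8.73 points without TGF-β1 replicate 1 and 1.23 points without TGF-β1 replicate 2. With 1 value per gene it was 1.89 against 0.371 points (adjusted p = 0.0396). The heat shock and ER chaperone list had a median of -0.320 against 0.280 points (permutation p = 0.0237, adjusted p = 0.130), and it passed without untreated replicate 1 (adjusted p = 0.0209). The matrix list had 1443 tested sites in 33 genes and 1 call, in TPM1, and the same site was called when adjusted over the list alone. No site was called over all tested sites by edgeR in the TGF-β signalling (423 sites), m5C enzyme and binding protein (90), earlier NSUN2 target (113), ribosomal protein (221), translation factor (164), glycolysis (212), chaperone (113), cell cycle (192) or nuclear long noncoding RNA (6) lists. Adjusted over the list alone, 1 chaperone site and 230 mitochondrial sites were called, and 0 in the other lists just named. Their adjusted p against random sets ran from 0.130 to 0.898.

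Cytosine coverage per gene, the stand-in for RNA abundance, rose for some known targets of TGF-β1 and did not pass for others. PMEPA1, a feedback inhibitor of TGF-β signalling, rose most among called genes, by 3.42 ± 0.31 on the log2 scale (SE), from 9.54 ± 1.36 to 116 ± 43.8 CPM, counts per 1e6 of shared coverage (SD, n = 2). The matrix protease MMP2 rose by 2.45 ± 0.25, the transcription factor JUNB by 2.38 ± 0.15 and TAGLN, a smooth muscle actin-binding protein, by 2.15 ± 0.20. RRAD (2.21), LMCD1 (2.15), WNT5B (2.15), PDGFB (2.13) and PTHLH (2.11) were further large rises. SFRP1, an inhibitor of Wnt signalling, had the largest fall among called genes, with a log2 fold of -3.43 ± 0.37 (SE), from 162 ± 43.4 to 14.7 ± 7.11 CPM. The other large falls were in ARHGAP35 (-3.02), MYLK (-2.99), NR2F2 (-2.93), PTX3 (-2.88), NEAT1 (-2.88), PALM2AKAP2 (-2.81), CITED2 (-2.75), TGOLN2 (-2.73) and F3 (-2.66).

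**Figure D5:**
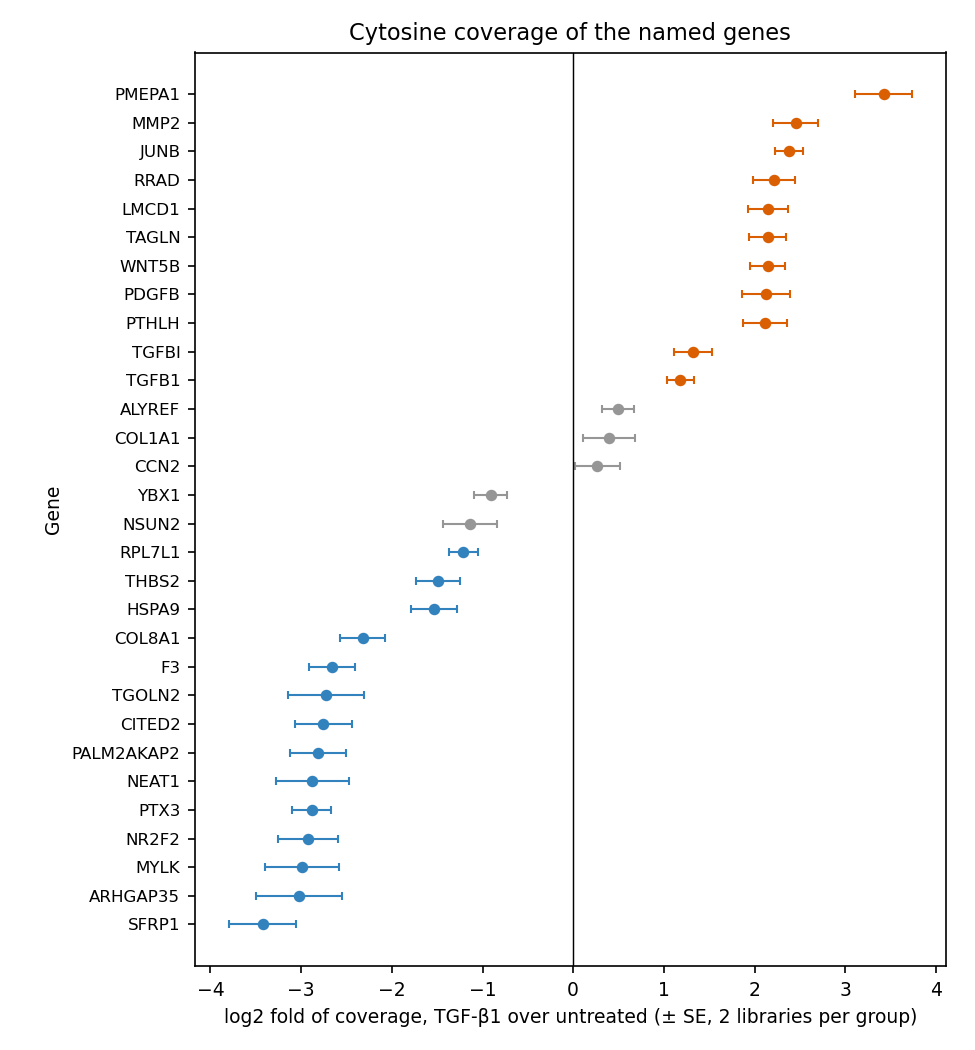
Points give the log2 fold of cytosine coverage, TGF-β1 over untreated, with SE bars from limma (2 libraries per group), for the named genes; orange genes rose, blue genes fell and grey genes did not pass the test. Values run from -3.43 for SFRP1 to 3.42 for PMEPA1.

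Of 7095 genes tested, 41 rose and 114 fell (limma, adjusted p under 0.05), and all 155 were separated between the groups, which selection by p favours (chance gives 33.3% for genes not selected). Of the falls, 9 were pseudogenes. Genes named whatever their result gave COL1A1 0.39 ± 0.29 (limma adjusted p = 0.355) and CCN2 0.27 ± 0.25 (0.467), matrix-linked targets of TGF-β, and neither passed. COL1A1 and CCN2 changed sign, to -0.03 and -0.08, without TGF-β1 replicate 1. NSUN2 stood at -1.14 ± 0.30 (adjusted p = 0.0735), and the m5C-binding proteins YBX1 at -0.91 ± 0.19 (0.0572) and ALYREF at 0.50 ± 0.18 (0.114). ACTA2 and NSUN6 had too few shared cytosines to be measured. Fold changes also followed stand-ins for GC share and exonic length. GC share was read from the 2 bases after each listed exonic cytosine. Length was that of the annotated exonic elements with a listed cytosine, so both depend on which cytosines were listed. Across genes, which are not independent replicates, Spearman's rho was 0.371 with GC share and -0.400 with length. Replicates of a group differed along the same stand-ins (-0.436 and 0.327 in untreated, 0.0469 and -0.448 in TGF-β1). The mitochondrial share of shared coverage was 0.603% and 0.629% in untreated and 0.447% and 0.296% in TGF-β1 libraries. Numbers of calls depended on the setting. TMM factors left 13 rises and 5 falls, so that 72.2% of calls were rises in place of 26.5%. The median log2 fold of all genes shifted by only 0.08 with TMM, and all 155 calls kept their sign. Without pseudogenes there were 19 rises and 17 falls. Called genes named here had limma adjusted p from 0.0339 to 0.0479. These lie near the threshold, so a small change in p can end many calls. By contrast, edgeR and DESeq2 on mean coverage gave 180 and 146 rises with 820 and 779 falls. Without TGF-β1 replicate 2 there were 26 rises and 65 falls, and without the others 48 to 307 and 519 to 1496.

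By preset list, 4 of 20 measured TGF-β signalling genes rose and 0 fell (8 and 3 adjusted over the list alone): PMEPA1, JUNB, TGFBI at 1.32 ± 0.21 and TGFB1 at 1.18 ± 0.15. Its limma camera test gave an adjusted p of 0.0519. TGFBR2 stood at -2.78 ± 0.58 (adjusted p = 0.0574) and SMAD3 at -1.58 ± 0.31 (0.0556). Of 36 matrix genes, MMP2 and TAGLN rose and COL8A1 (-2.32 ± 0.25) and the thrombospondin THBS2 (-1.49 ± 0.24) fell, while 32 did not pass (4 rises and 2 falls adjusted over the list alone). The matrix list was higher than other genes (median 0.25 against -0.12, camera adjusted p = 0.00613, but adjusted p = 0.585 with an estimated correlation, and 0.504 without TGF-β1 replicate 1 at the preset correlation).

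Genes with ribosomal protein symbols stood higher as a list (46 genes, among them relatives such as RPL7L1 and the kinase-like RPS6KL1, median 0.39, camera adjusted p = 4.85e-06, and adjusted p = 0.585 with an estimated correlation), although 0 rose singly and 1 fell, RPL7L1 at -1.21 ± 0.16, a relative of RPL7 (limma; 2438 of all genes tested had an unadjusted p under 0.05). The glycolysis list was higher as a whole (15 genes, median 0.26, camera adjusted p = 0.00284, and 0.585 as the adjusted p with an estimated correlation), with SLC2A1, a glucose transporter, at 0.83 ± 0.20 and HK2, a hexokinase, at -1.35 ± 0.25, and 0 called singly (5 rises and 1 fall adjusted over the list alone). The cell cycle list was lower as a whole (19 genes, median -0.72, camera adjusted p = 0.0493, and adjusted p = 0.585 with an estimated correlation), with the proliferation marker MKI67 at -3.68 ± 0.80 (adjusted p = 0.0583) and MCM6 at -1.82 ± 0.34, but CDK4 at 0.36 and MCM5 at 0.24, and 0 called singly (10 falls adjusted over the list alone).

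The remaining lists did not pass camera with either correlation. HSPA9, a mitochondrial chaperone, fell by 1.53 ± 0.25 on the log2 scale among 12 chaperones (3 falls adjusted over the list alone, median -0.48, adjusted p = 0.195). NEAT1 fell and MALAT1 stood at -2.23 ± 0.45 in the nuclear long noncoding pair (2 falls adjusted over the list alone, adjusted p = 0.0503). Of 13 translation factors 0 were called and 6 were lower when adjusted over the list alone (median -0.81, adjusted p = 0.380). Of 6 m5C enzymes and binding proteins 0 were called, with 1 rise and 3 falls adjusted over the list alone (adjusted p = 0.908), and of 4 earlier NSUN2 targets 0 by either adjustment (adjusted p = 0.380). Markers of other states were scarce: KRT7 (0.71) and SOX9 (-1.59) of 5 cholangiocyte markers were measured (adjusted p = 0.965), and NGFR (-0.70) and PDGFRB (0.97) of 9 markers of quiescent stellate cells (adjusted p = 0.901), each pair with 1 rise and 1 fall adjusted over the list alone.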

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

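Alternatives added after the data were seen were the deep-coverage, lone-site, pseudogene, trend, own-cytosine, per-gene and crossed settings, called sites without mitochondrial ones, and leaving out libraries for overlap, features and context; the other settings were planned. The unconverted share stayed higher in TGF-β1 libraries (0.0315 to 1.37 points) and candidate sites on shared cytosines more numerous (ratio 1.04 to 1.21) in every alternative run, with exact permutation p of 0.33 or 0.667 where all 4 libraries entered. Candidate numbers over each library's own listed cytosines went the other way. For candidate sites shared between libraries, the within minus between Jaccard difference of 0.00461 ran from -0.0263 to 0.0368 without single libraries. For the features of candidate sites, exon of a noncoding transcript turned to -0.00209 points at a level minimum of 20% and -0.00639 at a coverage minimum of 50; among the features of candidate sites, 3' UTR turned to -0.0690 at a coverage minimum of 50 and ran from -0.155 to 0.282 without single libraries, and downstream regions from -0.118 to 0.432. For features of candidate sites, coding sequence went from 0.511 points to 0.0669 at a coverage minimum of 50 and 0.0953 at a level minimum of 20%, with its separation lost, while features of candidate sites, downstream, reached 0.501 at the former and features of candidate sites, intron, -0.396 at the latter. The odds ratio of TCCA was 0.897 at a level minimum of 20%, 1.10 with clustered sites left out, 1.64 for lone sites and 1.51 for lone sites outside pseudogenes. The causes were not tested.

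Called sites (172 higher, 17 lower) numbered 50 and 9 at a coverage minimum of 10, 13 and 6 with pooled levels from 1%, 69 higher from 10%, 16 and 0 with clustered sites left out, 23 higher without mitochondrial sites, and 0 and 0 for lone sites or by the quasi-binomial model. In edgeR, 1595 sites had an unadjusted p under 0.05 with clusters left out. Fisher's exact test on pooled reads gave 197 and 17. Calls of at least 10 points (106 and 12) numbered 34 higher, 13 and 6, 65 higher, 6 and 0, 20 higher, and 0 and 0 in the same order. Leaving out single libraries gave 8 to 183 higher, 2 to 10 lower, and by 10 points 8 to 176 and 2 to 8. The median difference of level over tested sites, 0.43 points, was -0.0193 without TGF-β1 replicate 1. The cause was not tested. The site test's simulation recovered 0% of rises of 10 points, at sites with coverage of at least 100 too.

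List medians against random sets, none of them called, turned to 0.609 points for translation factors with means, 0.0787, -0.0547 and -0.537 for TGF-β, m5C and ribosomal genes at a coverage minimum of 10, and -0.306, 0.152 and 0.236 for ribosomal, matrix and cell cycle genes with 1 value per gene. Glycolysis reached -0.738 with means (adjusted p = 0.0137) and nuclear noncoding RNAs 2.78 at a coverage minimum of 10 (adjusted p = 0.00055). Without single libraries they ran from -0.262 to 0.0721 (translation factors), -0.309 to 0.264 (TGF-β), -0.790 to 1.17 (m5C), -0.0907 to 0.0106 (matrix), -0.267 to 0.0685 (cell cycle), -0.957 to -0.385 (chaperones, which passed at -0.957 without untreated replicate 1, adjusted p = 0.0209) and -0.395 to 0.0109 (NSUN2 targets). The mitochondrial list was called in every setting run, with a median difference from 1.23 points (without TGF-β1 replicate 2) to 8.73 (without TGF-β1 replicate 1). The cause was not tested.

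Gene coverage calls (41 higher, 114 lower) numbered 13 and 5 with TMM, 281 and 1141 for mean coverage, 194 and 1014 for highest coverage, 180 and 820 with edgeR, 146 and 779 with DESeq2, 226 and 1209 for own cytosines, 232 and 1033 for weighted own cytosines, 67 and 117 with the GC trend off, 205 and 274 with GC and length off, and 19 and 17 without pseudogenes. Leaving out single libraries gave 26 to 307 and 65 to 1496. The sign of all 155 calls held in each setting that tested them all. The median log2 fold of all genes shifted by 0.11 for mean and for highest coverage, 0.13 with edgeR, 0.10 with DESeq2, 0.08 with TMM, 0.14 for weighted cytosines, 0.21 with GC off and 0.18 with GC and length off. The log2 fold of gene CCN2 ran from -0.0847 to 0.62 and that of gene COL1A1 from -0.0305 to 0.81 without single libraries. The cause was not tested.

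List tests of gene coverage had these adjusted p. With an estimated correlation it was 0.585 for matrix, ribosomal, glycolysis and cell cycle lists. The cell cycle list reached 0.0970 with GC off, and nuclear noncoding RNAs 0.0495 with TMM, 0.0148 with GC off and 0.0346 with GC and length off. The TGF-β list reached 0.00573 with GC and length off. Directions turned for quiescent markers with GC off (0.916) and chaperones with GC and length off (0.957). Without single libraries the range was 2.56e-08 to 0.504 for matrix, 0.00737 to 0.0620 for cell cycle, 3.44e-05 to 0.168 for noncoding RNAs and 0.00018 to 0.504 for TGF-β. The cause was not tested.

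The replicate numbers do not establish pairing: deviations of same-numbered libraries correlated at -0.00425 for sites and -0.245 for genes. With the number as a block, 186 sites rose and 16 fell, 67 genes rose and 937 fell, and the adjusted p was 0.00523 for nuclear noncoding RNAs and 0.0330 for TGF-β. Crossed pairing for genes gave 190 and 877.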

Other observations

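The tests of explanations and the groupings in this part were chosen after the results were seen. Settings quoted here that the section above counts as planned are the exception. Lone sites of high level, which stand apart from the clusters, were found in JPH2 (3' UTR, chromosome 20, 44112790, 97.98% ± 2.07, SD, n = 4), PLXNA1 (3' UTR, chromosome 3, 127036974, 95.9% ± 1.25), ANKRD9 (5' UTR, 93.2% ± 5.65), TADA3 (intron, 92.9% ± 1.24) and OGFOD3 (3' UTR, 86.4% ± 2.27). Further on came SPATA20 (81.2% ± 4.98), the protease FURIN (3' UTR, chromosome 15, 90882311, 80.3% ± 2.31) and an intron of MMP14, a membrane-bound matrix protease (chromosome 14, 22846957, 78.8% ± 3.29). Among lone candidates none was called between the groups when they were tested alone (edgeR, 2471 sites, 0 called, 114 at an unadjusted p under 0.05), although 4 of the calls over all tested sites were lone. The lone JPH2 site lies in the same 3' UTR as the called site at 44112533, which fell.

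Lone sites followed by TCCA were spread unevenly over levels. They made up 0.311% of 1930 sites at 10% to 20%, 1.62% of 308 at 20% to 30%, 4.67% of 150 at 30% to 50% (7 sites, exact 95% interval 1.90 to 9.38%) and 1.27% of 79 above 50%, against 0.472% of cytosines that were candidates in no library. The sites of highest level were in FURIN, in an intron of MAPK3 (chromosome 16, 30117206, 41.8% ± 7.24, SD, n = 4) and in the coding sequence of PLD3 (chromosome 19, 40367744, 38.4% ± 7.35). Taken per library, lone candidates showed no excess of TCCA (odds ratios 0.974 and 0.680 in untreated, 0.689 and 0.766 in TGF-β1 libraries), and no explanation was tested.

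Mitochondrial minus-strand cytosines were 9.76% unconverted in TGF-β1 replicate 2. Poorer conversion of that library as a whole is argued against by its nuclear unconverted share, 2.66%, below the 2.79% of TGF-β1 replicate 1. Unconverted double-stranded DNA is argued against by the excess of unconverted reads per cytosine over untreated replicate 1, which was 0.132 times as large on the plus strand as on the minus strand. Unconverted minus-strand reads came to 84.7 CPM in this library and 68.6 and 98.2 in untreated ones, while converted reads fell to 784 CPM from 2664 and 2704. A pool of unconverted reads of steady size is a candidate explanation. These totals also hold ordinary failures of conversion, which shrink as coverage falls. They therefore cannot show whether such a pool kept its size or grew. What formed any such pool, and whether TGF-β1 or the handling of this library lowered the converted reads, stays open because the labels give no batch and TGF-β1 replicate 1 had 61.9 unconverted and 1444 converted CPM.

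In the CENPB 5' UTR, a difference between the groups in conversion, or in denaturation of all folded RNA, would by itself move all sites 1 way. Of the called 5' UTR sites 10 fell and 16 rose (13 falls with 3 sites of the coding sequence), so neither alone accounts for all of them. These opposite directions were the pattern that prompted the question, so they are not a separate test, and neither explanation is excluded as a part. Reads of another source, added in treated libraries, would raise coverage of the cluster relative to the 5' UTR beyond it. Mean coverage of its 32 cytosines relative to the 43 from 3786567 to 3786719 gained 1.52 and 1.51 fold in the TGF-β1 libraries. Called sites that rose need a median factor of 1.74 (SD 0.165) and 13 of 16 need more than the larger gain. By that measure such reads are argued against as the whole cause of the rises. For the falls this cannot be told apart, as the median needed is 1.24 (SD 0.409) but 3 of 10 sites, with the largest falls among them, need more than the gain. Both readings assume that coverage outside the cluster tracks the original reads and that 1 mean holds for the whole cluster. The gain depends on the region compared. From untreated to TGF-β1 replicate 1, mean coverage went from 139 to 114 over the 43 cytosines, but from 119 to 122 over the 14 from 3786580 to 3786624. Inside the cluster it went from 137 to 177 over the 5 from 3786526 to 3786534, and from 162 to 177 over the 9 from 3786551 to 3786561. This test took several forms in turn, each set after values were seen: the single fall that needed most needed 2.12, the 26 called 5' UTR sites together needed a median of 1.59 (SD 0.298), too close to 1.52 to decide, and the split by direction and the demand that every site be covered came last. A change in the folding or start of this RNA after TGF-β1 was not tested, and library handling stays open beside it.

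In gene coverage 114 genes fell after TGF-β1. For the listing of only those cytosines with an unconverted read, 99.1% of the 114 falls were still called on each library's own cytosines weighted for unlisted ones. That setting called 1033 falls in all, so a strong fall is likely to stay called in it whatever the cause. It also only reweights listed cytosines of genes already chosen. Whether the listing contributed cannot be decided from it. For a GC and length trend, 76.3% (87 of 114) stayed called with both trends taken off. That setting called 274 falls in all, so staying called decides little here too. The median log2 fold of the 114 went from -1.78 (SD 0.493) to -1.20 (SD 0.534). The trends as fitted therefore did not carry the whole size of these falls. Effects of GC or length that the stand-ins from listed cytosines miss stay open. The other 27 calls ended because the fold shrank, from a median of -1.47 (SD 0.275, median SE 0.23) to -0.61 (SD 0.172, median SE 0.20), so the trends may carry part of the size. The excess of falls over rises is another matter and is not explained by this test: it varied with the setting, from 41 rises and 114 falls to 205 and 274 with both trends off, 281 and 1141 for mean coverage, 180 and 820 with edgeR and 19 and 17 without pseudogenes. TMM scaling gave 13 and 5 with a shift of 0.08 in the median log2 fold of all genes. Treatment, library handling and the listing of cytosines remain open for the rest.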
